A study of Caenorhabditis elegans with 2 samples.

How the data were processed

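ChIP-seq was done on chromatin of whole late C. elegans embryos, with sonication and an antibody against GFP, in 2 biological replicates numbered in the labels. They form 1 group. Per the labels, sexes were pooled and a control library was used; the control was not analysed here. Per the labels the strain carries an mNG and 3xFlag insertion at pat-9, while the description and a note in the labels name an eGFP fusion and a C-terminal GFP-FLAG tag, and these fields cannot all hold.

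Per the descriptive text deposited with the lists, the regions of each replicate were called on that replicate's alignments with a control alignment, the pooled list on both replicates' alignments with the control, and the optimal list was derived from these 3 lists by IDR. All are narrowPeak lists on ce11. The replicate and pooled lists hold 30000 regions each, before any threshold, so weak regions in them are background by construction. The aligner, peak caller, versions and IDR threshold are not given in the sources used here. The authors' deposited signal value per region is used only to describe, rank or filter regions within a list. The authors' deposited −log10 q per region reached a maximum of 2.91 in the optimal list, which 411 of its 735 peaks shared, so it does not rank the strong peaks. No p-value is filled in. Summits come from the summit offset column. In the optimal list 548 peaks are 430 bp wide, widths run from 108 to 592 bp, and 4 rows share coordinates with another row and differ in summit. Depth per sample is unknown, and the number of replicates limits the precision.

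Annotation was Ensembl release 115 on WBcel235, the same assembly as ce11, and sequence was the matching RefSeq assembly. Every region ended within its chromosome, for example at 17716916 on X, which is 17718942 bp long. tRNA genes carry no symbol in this annotation. Regions were ranked by signal. Promoter windows ran from 1000 bp upstream to 500 bp downstream of the 5′ end of any protein-coding transcript, and a summit could belong to several genes. Small RNA genes were tRNA, rRNA, snRNA and snoRNA genes, with a summit within 200 bp. Location classes were assigned in the order small RNA gene, coding exon, 5′ UTR, 3′ UTR, upstream within 1000 bp, intron, other intergenic.

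Optimal peaks were compared with the 29038 pooled regions that overlap no optimal peak, by two-sided Fisher's exact tests. Odds ratios are conditional estimates with exact 95% intervals. Percentages carry Wilson 95% intervals where one is given, and these cover counting error only. Gene lists were tested among the 8678 of 19973 protein-coding genes with a pooled region in the promoter window, with Benjamini-Hochberg adjustment over 20 lists. Of the list symbols 1 (unc-110) had no match and was left out. Correlations and the signal comparison used permutation tests with 100000 resamples, two-sided. Each of 2080 6-mers (with reverse complements joined) and 8 fixed motifs was tested in 101 bp at the summit against a 101 bp window 200 bp away by an exact McNemar test, with Benjamini-Hochberg adjustment. For base composition, odds ratios were combined over strata of 5 percentage points of GC by the Mantel-Haenszel method. P-values over peaks and genes describe this peak list and not the spread between embryos. The work used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.

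The main tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. Tests of the 4 muscle lists together, of chromosomes other than X, of location classes and of each small RNA class were not among those fixed. Named were pat-9, the genes of the 20 optimal peaks with the highest signal, up to 4 bound members of each list with the highest signal, all bound and up to 6 unbound members of the 4 muscle lists, and the 10 6-mers with the smallest p. Names in the observations that fall outside this rule were chosen after their values were seen, as were the snoRNA genes named with the strongest peaks. Alternatives were the stronger 50% and double the number of peaks, leaving out each replicate, other promoter windows and gene assignments, other backgrounds, matched random lists, other overlap rules and other motif windows. Leaving out summits near small RNA genes was added after seeing the data.

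The list test and the motif test were tested on simulated data. Of 200 simulated lists without enrichment 0 were called, and all 20 lists with 7 of 30 members bound were. At random genome positions with nothing planted 0 6-mers were called, and of 5 6-mers planted in 60 of these positions each 4 were recovered. Real summits held more GC than their flanks (50.5% against 37.8%). The simulation therefore does not show how many 6-mers base composition alone would call. Simulated lists were drawn without regard to the number of regions per promoter, so that influence was not covered either.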

Results

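Chromatin immunoprecipitation and sequencing (ChIP-seq) for tagged PAT-9 was done in whole late embryos of Caenorhabditis elegans, strain RW12085, whose age label reads 3 hours. PAT-9 is a C2H2 zinc finger transcription factor that is needed for the development of body wall muscle. The data hold 1 group of 2 biological replicates and no second condition, so the design asks where in the genome the immunoprecipitate was enriched and how well the replicates agreed. The labels disagree on the tag: the strain is described as a CRISPR insertion of mNG and 3xFlag, while other fields name a GFP fusion, and the immunoprecipitation used an antibody against GFP. mNG, mNeonGreen, is a fluorescent protein that is not derived from GFP, and antibodies against GFP usually do not recognise it. The authors deposited 30000 regions for each replicate, 30000 regions for the pooled reads and 735 optimal peaks that passed their reproducibility filter (IDR). Read depth is unknown from these lists, and all signal values are the authors' own, on a scale that holds within a list. Coordinates are on build ce11.

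The strongest sites in the embryo lay beside snoRNA genes, the templates of small RNAs that guide the modification of ribosomal and other RNAs. Of the 20 optimal peaks with the highest signal, 9 had their summit within 200 bp of an annotated snoRNA gene and 1 within 200 bp of a tRNA gene. The top peak, on chromosome II from 11960633 to 11961033, had a signal of 991 and lay at snoRNA gene W03C9.9, with W03C9.1 the nearest protein-coding gene start. The next, on chromosome V from 12303434 to 12303843, had a signal of 964 and lay inside frm-7 at snoRNA genes C51F7.4 and C51F7.3. Further snoRNA peaks lay inside cutl-18, pxn-1, a peroxidasin gene, Y43F8C.7 and the MAP kinase gene mpk-2, in the promoter windows of sre-23 and T02E1.2, and 1395 bp downstream of the start of str-56, with signals from 450 to 750. The tRNA peak in this set, with a signal of 492, was nearest to C04A11.5.

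The remaining 10 of the 20 strongest peaks were mostly promoter sites of protein-coding genes, though some of them had the summit at another noncoding RNA gene, as described below. K12H4.5 (signal 593), the ribosomal protein gene rpl-3 (562), ears-2 with uncp-18 (499), the ataxin-2 gene atx-2 with ecps-1 (458), T13C5.6 (454), tasp-1 with K01G5.10 (453) and the 14-3-3 gene ftt-2 (449) had the summit within 526 bp of a start. For rpl-3 the peak covered positions 3867424 to 3867733 of chromosome III, with the summit 269 bp upstream of the start. The other sites lay in an intron of ints-8, which codes for a subunit of the Integrator complex (473), and in intergenic sequence nearest to hrg-5 (493) and nas-30 (486). Across the 735 optimal peaks the median signal was 137 and the lowest was 101.3, and the optimal peaks were exactly the 735 pooled regions with the highest signal.

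The replicates ranked the strongest sites alike and diverged at weaker ones. The peaks at W03C9.9, at C51F7.4 with C51F7.3 and at T03F7.8 held ranks 1, 2 and 3 in each replicate's own list. Of the 735 strongest regions of replicate 1, 464 overlapped the 735 strongest of replicate 2 by at least 1 bp, a share of 63.1% (Wilson 95% interval 59.6 to 66.5%), against a mean of 1.47% and a maximum of 2.86% in 1000 random draws from the full lists. Among the optimal peaks, 530 (72.1%, 68.8 to 75.2%) lay in replicate 1's own strongest 735 and 631 (85.9%, 83.1 to 88.2%) in those of replicate 2. Every optimal peak overlapped a region in each replicate's list, the weakest at rank 17044 in replicate 1 and 3208 in replicate 2. Signal values of the replicates correlated across the 735 peaks, with Spearman's rho of 0.635 and Pearson's r of 0.745 on log2 values (permutation p = 1e-05 for each, two-sided, the smallest that 100000 resamples can give). Peaks are not independent replicates, and selection on the pooled signal shapes this correlation. Without summits near small RNA genes, a setting chosen after seeing the data, the overlap was 48.8% and rho was 0.426.

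**Figure D1:**
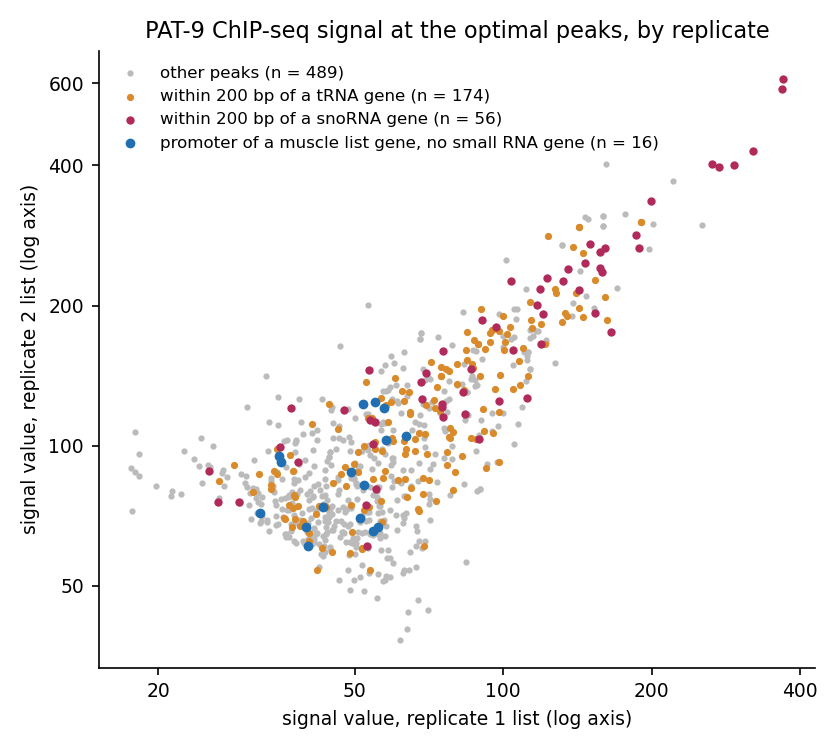
Signal value of each of the 735 optimal peaks in the replicate 1 list (x axis, log scale) and in the replicate 2 list (y axis, log scale), both in the authors' own units; each point is a peak. Points within 200 bp of a snoRNA gene (n = 56) reach the upper right corner.

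Small RNA genes lay beside many of the other sites as well, and in all 241 of 735 optimal peaks (32.8%, Wilson 95% interval 29.5 to 36.3%) had the summit within 200 bp of a tRNA, snoRNA, snRNA or rRNA gene. The same held for 357 of the 29038 other pooled regions (1.23%), which gives an odds ratio of 39.2 (exact 95% interval 32.4 to 47.4, Fisher's exact test, two-sided, p = 4.7e-236). tRNA genes accounted for 174 peaks (odds ratio 40.6, interval 32.5 to 50.7), snoRNA genes for 56 (22.7, 15.97 to 32.0) and genes annotated as snRNA, which include the sls-2 genes of the spliced leader RNA used in trans-splicing, for 12 (15.04, 7.02 to 30.1). The largest of their adjusted p-values by Fisher's exact test was 6.4e-10. Counted by gene, 181 of 612 tRNA genes (29.6%, 26.1 to 33.3%), 57 of 346 snoRNA genes (16.5%, 12.9 to 20.7%) and 10 snRNA genes (7.75% of that class, 4.26 to 13.7%) had a peak. None of the 20 rRNA genes did, and no other pooled region lay near them either. In each replicate's own 735 strongest regions the share near small RNA genes was 29.1% and 31.8%.

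The summit sat at a different place in the 2 main classes. At tRNA genes, whose promoter elements lie inside the transcribed sequence, 108 of 181 genes (59.7%) had the summit inside the gene, and the median position was 17 bp downstream of the 5′ end (quartiles -10 and 43 bp). At snoRNA genes 51 of 57 (89.5%) had it upstream, and the median position was -46 bp (quartiles -58 and -32 bp). The median signal of the peak was 275 over these snoRNA genes and 178 over the tRNA genes. These counts describe genes that have a peak, and the difference between the classes was not tested.

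**Figure D2:**
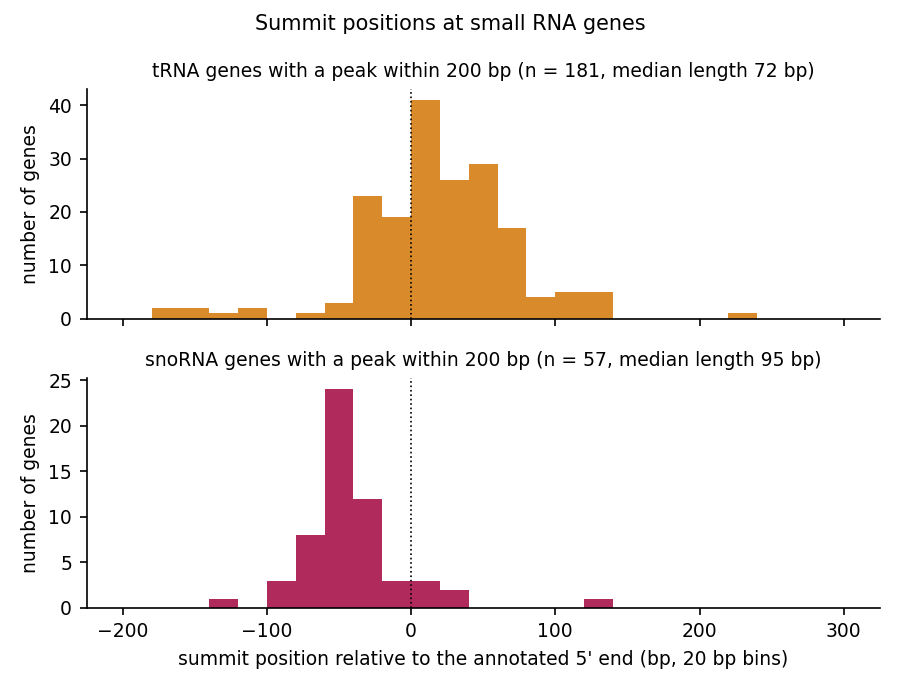
Number of genes (y axis) by summit position relative to the annotated 5′ end in bp (x axis, 20 bp bins, negative values upstream), for 181 tRNA genes (top) and 57 snoRNA genes (bottom) with an optimal peak within 200 bp. tRNA summits centre just inside the gene at a median of 17 bp, and snoRNA summits upstream at a median of -46 bp.

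Promoters of protein-coding genes and chromosome X held more of the optimal peaks than of the other regions. Coding exons and introns held fewer when summits near small RNA genes were counted apart. Summits fell in a promoter window, from 1000 bp upstream to 500 bp downstream of a transcript's 5′ end, for 395 of 735 optimal peaks (53.7%) and for 10627 of 29038 other regions (36.6%; odds ratio 2.01, interval 1.73 to 2.34, Fisher's exact test, p = 1.4e-20). Without summits near small RNA genes, a setting chosen after seeing the data, this odds ratio was 3.24. Chromosome X held 195 optimal peaks (26.5%) and 15.1% of the other regions (odds ratio 2.03, 1.71 to 2.40, Fisher's exact test, p = 4.1e-15). Chromosomes II and V held fewer peaks than the background (odds ratios 0.74 and 0.75, adjusted p = 0.014 for each by Fisher's exact test), and chromosomes I, III and IV did not pass the test. Since an excess on X lowers the shares of all other chromosomes, these deficits are not separate from the X result. By location class, 11 peaks (1.497%) fell in coding exons against 20.3% of other regions, and 57 (7.76%) in introns against 28.6%. Summits near a small RNA gene were put in that class first, even inside a protein-coding gene. That class took 32.8% of optimal peaks and 1.23% of other regions, so these contrasts are enlarged by the order. Upstream sequence within 1000 bp that was not near a small RNA gene held 297 peaks (40.4%) against 21.7%.

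**Figure D3:**
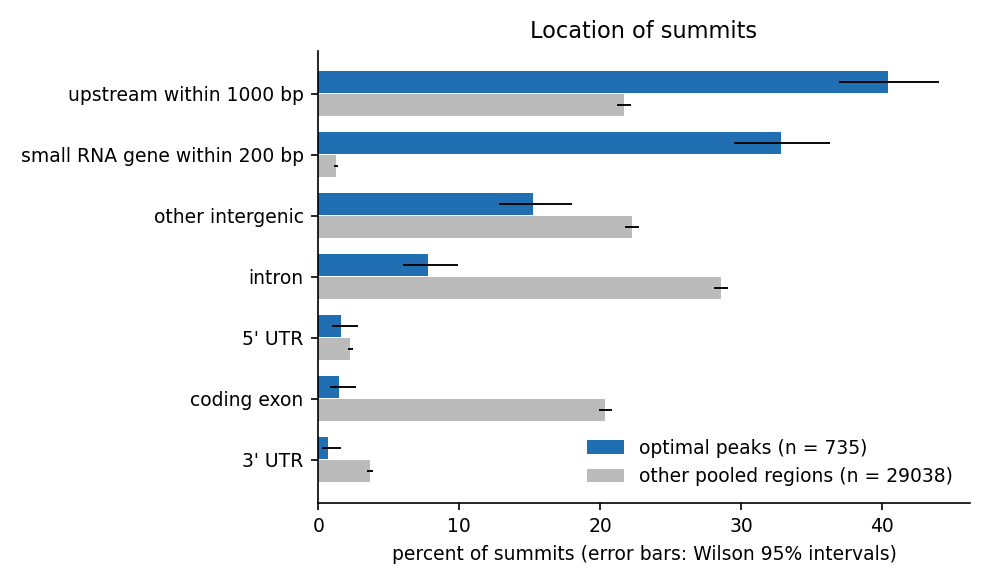
Percent of summits (x axis) in each location class for the 735 optimal peaks and the 29038 other pooled regions; error bars are Wilson 95% intervals and classes are exclusive. Optimal peaks exceed the other regions upstream of genes (40.4% against 21.7%) and at small RNA genes (32.8% against 1.23%), and fall below them in introns and coding exons. Summits near a small RNA gene count in that class only.

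Muscle genes, the tissue PAT-9 is known for, had promoter peaks above background. The sarcomere list, which holds the thick and thin filament genes, had a peak at 7 of 27 background members (25.9%), against 513 of all 8678 background genes (5.91%), an odds ratio of 5.63 (2.00 to 13.9, adjusted p = 0.0076 over 20 lists by Fisher's exact test). Bound members were the paramyosin gene unc-15 (signal 177, summit 130 bp upstream of the start), the troponin C gene pat-10 (169), the myosin light chain genes mlc-1 (161), mlc-3 (134) and mlc-2 (115), and the troponin T genes mup-2 (131) and tnt-2 (127). The unc-15 peak covered positions 7383112 to 7383541 of chromosome I and the pat-10 peak 5019980 to 5020409 of the same chromosome. Several unbound members lay just below the threshold: the actin genes act-3 and act-1 had the strongest pooled region of their promoter window at ranks 756 and 786, act-4 at 1274 and the myosin heavy chain gene unc-54 at 1073, while myo-3 and act-2 were at 6212 and 8558. The sarcomere result did not pass with the stronger 50% of the optimal peaks (odds ratio 4.25, adjusted p = 0.42 by Fisher's exact test). It did not pass against random lists matched on the number of pooled regions per promoter either (ratio 3.63, adjusted permutation p = 0.058).

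The list of attachment genes, whose products anchor filaments at dense bodies and M-lines, had 5 of 22 members bound, with an odds ratio of 4.72 (1.35 to 13.4) and an adjusted p of 0.052 by Fisher's exact test. These were dim-1 (179), unc-112, a kindlin gene (173), unc-23 (125), the zyxin gene zyx-1 (118.9) and the talin gene tln-1 (107). This list passed without replicate 1 (odds ratio 4.91, adjusted p = 0.046 by Fisher's exact test) and not without replicate 2 (3.84, adjusted p = 0.12, Fisher's exact test). The integrin gene pat-3 was not bound but had its best region at pooled rank 1236, ahead of act-4. The adhesion genes pat-4 (rank 2221), pat-6 (3242), unc-97 (3385) and unc-95 (18356) were not bound either. The integrin gene pat-2 had no pooled region in its promoter window and so was not among the 22. Among excitability and neuromuscular junction genes 3 of 23 were bound (odds ratio 2.40, adjusted p = 0.43 by Fisher's exact test): the potassium channel gene unc-58 (171), at a site within 200 bp of a tRNA gene, rsu-1 (130) and the acetylcholine receptor gene unc-29 (102). Without replicate 2 the odds ratios of this list and of the myogenic factors were 0.82 and 0. The calcium channel gene egl-19, unc-68, unc-63 and lev-8 were not bound. No pooled region lay in the promoter windows of unc-38 and lev-1, so they were not among the 23. Of the myogenic and mesodermal transcription factors 2 of 15 were bound (2.45, adjusted p = 0.53 by Fisher's exact test), the homeobox genes unc-62 (118) and ceh-20 (106). The MyoD homologue hlh-1 had its best region at pooled rank 863, the SRF homologue unc-120 at 2531 and tbx-8 at 16787, all unbound. No pooled region lay in the promoter windows of hnd-1 and pal-1, so they were not among the 15. Over the 4 muscle lists together 17 of 87 genes were bound (19.5%, odds ratio 3.96, 2.17 to 6.87, Fisher's exact test, p = 1.0e-05). This joint test was not among those fixed beforehand, and its p is not adjusted over the lists. The peaks of these muscle genes did not differ detectably in strength from the other 378 promoter peaks, with a difference in mean log2 signal of -0.20 (7.08 ± 0.28 against 7.28 ± 0.56, SD over peaks, permutation p = 0.15). Of the 17, those outside replicate 1's own strongest 735 were ceh-20 (rank 2339), rsu-1 (1667), mlc-3 (1590), tln-1 (1024), unc-29 (990) and unc-62 (773). Outside those of replicate 2 were unc-29 (897) and zyx-1 (738).

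The pat-9 gene itself, on chromosome X from 16536890 to 16540213, had no optimal peak. Its strongest pooled region, from 16536277 to 16536706 with the summit 398 bp upstream of the gene, had a signal of 83.7 and pooled rank 1135. The strongest region there ranked 2486 in replicate 1 and 1074 in replicate 2.

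Ribosomal protein genes, which are transcribed in all tissues, had a peak in 14 of 73 promoters (19.2%, odds ratio 3.85, 1.97 to 7.05, adjusted p = 0.0016 by Fisher's exact test). The strongest of the 13 distinct peaks were at rpl-3 (562), rpl-15 (353), rpl-35 (261) and rpl-20 (230). Chemoreceptor genes, which are expressed mainly in sensory neurons, were bound in 5 of 233 cases (odds ratio 0.34, 0.11 to 0.82, adjusted p = 0.052 by Fisher's exact test), with the highest signals at sre-23 (695), sre-1 (286), sri-5 (181) and srh-269 (150).

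Few markers of other tissues were bound at the authors' threshold, and no list among them passed the test. With double the number of peaks their shares lay near or above the 11.3% of all background genes for pharyngeal muscle (25%), pan-neuronal (14.3%) and hypodermis (11.5%), and these did not pass either. No member was bound among the genes with a pooled region in the promoter window, 12 of 21 pharyngeal muscle, 9 of 29 intestine and 12 of 34 germline genes. The pan-neuronal list had 1 of 21 bound (syd-2, 125) and the hypodermis and embryonic cuticle list 1 of 26 (ajm-1, 124). Basement membrane genes had 2 of 17, ost-1 (280) and the collagen IV gene let-2 (111), and secreted signals and guidance cues 2 of 11, the FGF gene egl-17 (323) and the semaphorin gene mab-20 (101.3). Histone genes had 4 of 29 bound from 2 peaks, his-67 with his-68 (213) and his-31 with his-32 (127). The rest were proteasome with 1 of 20 (rpn-7, 169), cuticle collagens with 2 of 72 (col-85, 348, and col-185, 168), neuropeptides with 1 of 59 (flp-23, 130), nuclear hormone receptors with 4 of 102 (nhr-255, 259, nhr-47, 145, nhr-142, 120, and nhr-48, 111), homeobox ceh genes with 1 of 35 (ceh-20) and C-type lectins with 2 of 64 (clec-53, 207, and clec-126, 180). The smallest adjusted p among these lists was 0.36 by Fisher's exact test, for histones. Several of these promoter peaks had the summit within 200 bp of a tRNA gene: those of ajm-1, egl-17, col-85, col-185, flp-23, nhr-255, clec-126 and the chemoreceptor gene srh-269. Without summits near small RNA genes, 0 hypodermis, collagen and neuropeptide genes were bound.

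**Figure D4:**
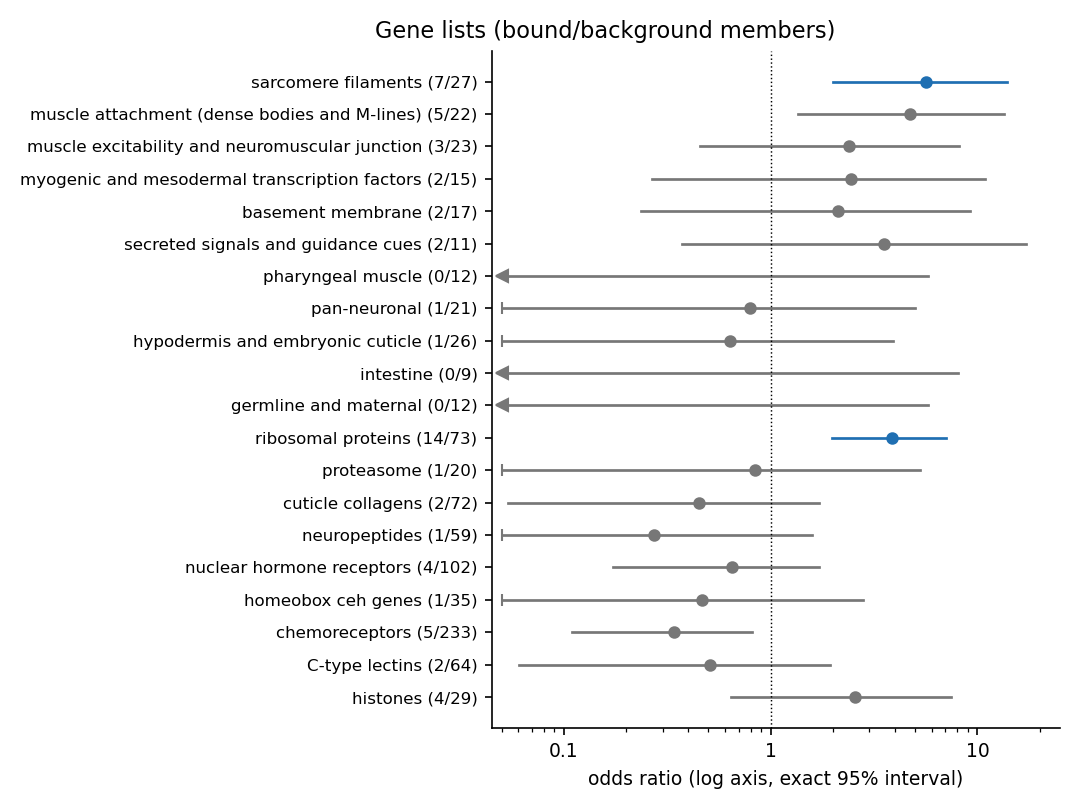
Odds ratio of having an optimal peak in the promoter window (x axis, log scale, exact 95% interval) for each of the 20 gene lists, with bound and background members in brackets; blue marks an adjusted p below 0.05, arrows mark an odds ratio of 0 and ticks an interval that goes on past the axis. Sarcomere filaments (5.63) and ribosomal proteins (3.85) are the lists that passed.

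Summits were richer in G and C than the sequence beside them. The window centred on the summit held 50.5 ± 7.23% GC (SD, n = 735 peaks), windows 200 bp away 37.8 ± 9.68% and other pooled summits 40.9 ± 8.95% (n = 29038). Of 2080 6-mers, 398 were enriched and 298 depleted at summits against the same locus 200 bp away (exact McNemar test, Benjamini-Hochberg adjusted), and 265 were enriched without replicate 2. The 10 with the smallest p held 7 AT-rich depleted words (AAAATT, AAAAAT, AAATTA, AATAAA, TAAAAA, TGAAAA and TTGAAA) and 3 enriched words. AAAATT was present at 11.3% of summits and 38.8% of flanks. Enriched were CGAACC (13.1% against 1.90%), GTTCGA (15.5% against 3.40%) and ACGCGC (12.4% against 1.63%), and the largest adjusted p of the 10 by the exact test was 3.0e-14. GTTCGA is part of the internal B box of tRNA genes, and CGAACC, read as GGTTCG on the other strand, shares GTTCG with it. Without summits near small RNA genes, a setting chosen after seeing the data, other words led the enriched ones. These were CGCCGC (17.4% against 3.04%), CGCGCC (13.4% against 1.62%) and CGCGCA (16.6% against 3.04%).

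Of 8 motifs fixed for known regulators, the GA repeat GAGAGA was enriched, at 19.5% of summits and 9.25% of flanks (adjusted p = 3.7e-08, exact McNemar test), a difference of 10.2 percentage points that was 5.85 with 51 bp windows. The GATA site TGATAA, bound by gut regulators, was depleted, at 3.13% against 10.3% (adjusted p = 2.4e-07, exact McNemar test), a difference of -7.21 percentage points that was -3.27 with 51 bp windows and -3.13 against other pooled summits, which are closer in GC content than the flanks. The E-box CANNTG, bound by HLH-1 and other bHLH factors, was at 34.8% against 29.4% and did not pass (adjusted p = 0.079, exact McNemar test), but passed without replicate 1 (difference 6.26 percentage points, adjusted p = 0.032, exact McNemar test) and not without replicate 2 (2.45, adjusted p = 0.48, exact McNemar test). The E-boxes CAGCTG (2.86% against 2.45%) and CACCTG (2.18% against 2.99%), the SRF-type site CCWWWWWWGG (0% against 0.41%), the forkhead site TRTTTRY (15.8% against 18.6%) and the AP-1 site TGASTCA (0.27% against 1.22%) did not pass either, but the depletion of the forkhead site passed without replicate 2 (difference -5.71 percentage points, adjusted p = 0.0092, exact McNemar test). The depletion of the SRF-type site passed with double the number of peaks (-0.61 points, adjusted p = 0.045) and against other pooled summits (-0.78, adjusted p = 0.021), by exact tests.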

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

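Of the results recomputed under alternatives, none that passed its threshold changed direction. The separate tests of chromosomes other than X, of location classes, of each small RNA class and of the muscle lists together were not recomputed. The excess of optimal peaks in promoters, on X and at small RNA genes, the replicate correlation and the missing signal difference of muscle peaks kept their direction and their side of the threshold under every alternative run (odds ratios from 1.75 to 3.24, 1.65 to 2.18 and 24.7 to 59.1). The enrichment of ribosomal protein genes did so too (odds ratios from 3.24 to 8.12, and a ratio of 3.22 to matched random lists). The sarcomere list lost its call with the stronger 50% of the peaks (odds ratio 4.25) and against matched random lists (ratio 3.63), where 1 list stayed enriched each time in place of 2. Halving the list leaves fewer bound genes, and matching takes the number of regions per promoter into account. Its adjusted p ran from 2.3e-08 to 0.42 over the alternatives, by exact and permutation tests, and without replicate 1 or 2 its odds ratio was 6.52 or 8.18; the highest, 14.4, came with the nearest gene start. The number of enriched 6-mers fell from 398 to 254 with the stronger 50% of the peaks, 235 without small RNA genes (chosen after seeing the data) and 213 with 51 bp windows, and was 265 to 406 with 1 replicate left out, the lowest without replicate 2; it rose to 503 with double the number of peaks and 535 against other pooled summits. Enriched fixed motifs went from 1 to 2 with double the number of peaks, and were 1 to 2 with 1 replicate left out, the second being the E-box CANNTG. The replicate overlap moved from 63.1% to 50.9% with reciprocal overlap of 50%, 57.01% with summits within 100 bp, 75% with the number of regions halved, 53.0% with it doubled and 48.8% without small RNA genes; beyond the construction of these settings the cause was not tested. Values that passed no threshold changed direction 17 times, and the cause was not tested. Odds ratios did so with the stronger 50% of the peaks for myogenic factors (0), proteasome (1.78) and C-type lectins (1.09). With double the number of peaks they did so for pharyngeal muscle (2.63), pan-neuronal (1.31) and hypodermis (1.03), and with the 2000 bp window for pan-neuronal (1.21) and proteasome (1.32). Pan-neuronal also did with gene bodies (2.06), the nearest start (1.36) and all protein-coding genes (1.36), the last with hypodermis (1.08) and proteasome (1.19). With 1 replicate left out the odds ratios were 0.82 to 1.75 for excitability, 0 to 4.16 for myogenic factors and 0.83 to 1.07 for pan-neuronal genes, each changing without replicate 2. The forkhead difference was 1.56 percentage points against other pooled summits. Among the other values 231 kept their call and 17 passed a threshold that the main setting missed, among them attachment genes (5 settings) and the depletion of chemoreceptors (7 settings). No paired analysis was possible because there is 1 group. Depth is unknown, so what it limits could not be given.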

Other observations

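The comparisons of muscle with ribosomal protein genes and with markers of other tissues, the tests of identical copies and the test of X without small RNA genes were chosen after the results were seen; the tests of GC content were set down before their values were seen.

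Sarcomere genes were frequent just below the authors' threshold. With double the number of peaks (1470 regions), 15 of 27 sarcomere genes had a promoter peak in place of 7, while bound background genes rose from 513 to 978, and the odds ratio was 9.97 (interval 4.34 to 23.4). Among the added genes were act-1, act-3, act-4, unc-54, the tropomyosin gene lev-11 (pooled rank 1261), the cofilin gene unc-60 (830) and the giant muscle protein genes unc-89 (926) and unc-22 (965). Attachment genes went from 5 to 7 of 22, excitability genes from 3 to 5 of 23 and myogenic factors from 2 to 4 of 15, the last with hlh-1 and pat-9 itself. Other lists rose as well: ribosomal protein genes went from 14 to 24 of 73 and pharyngeal muscle genes from 0 to 3 of 12, and differences between the rises were not tested.

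Among the 20 strongest peaks, some that lay near no tRNA, snoRNA, snRNA or rRNA gene had the summit at another noncoding RNA gene; they were chosen after their values were seen, and an excess at such genes over all peaks was not tested. The peak of rank 14, in an intron of ints-8, had its summit 23 bp downstream of the 5′ end of rpr-1, the RNA component of RNase P, on chromosome I from 13463955 to 13464207 (signal 473). The peak of rank 17, assigned to T13C5.6, had its summit 19 bp inside the noncoding RNA gene C14F11.14 (454), and the peak of rank 20, assigned to ftt-2, had it 51 bp inside F52D10.7 (449). The summit of rank 11 lay 14 bp inside F36H1.17 and 93 bp upstream of the microRNA precursor cel-mir-51 (493). Of the 100 strongest peaks 62 were near a tRNA, snoRNA, snRNA or rRNA gene, 28 of them near a snoRNA gene.

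The first pattern is the concentration of peaks at small RNA genes. Base composition alone does not account for it, since the odds ratio stratified by GC content of the summit was 24.7 (20.1 to 30.3), down from 39.2. Reads shared between exact full-length copies of a gene cannot account for the snoRNA part. All 57 snoRNA genes with a peak were single-copy by that measure, as were 343 snoRNA genes in all, and the odds ratio there was 22.9 (16.1 to 32.3). Partial or near-identical copies were not examined, nor were copies of the upstream sequence that held most snoRNA summits, so shared reads of those kinds stay open. For tRNA genes reads shared between identical copies stay open. Genes with an identical copy had a peak more often (158 of 472) than single-copy genes (23 of 140), an odds ratio of 2.56 (1.55 to 4.36). Yet peaks at single-copy tRNA genes were also in excess (16.6, 9.80 to 27.2). Signal from open, heavily transcribed loci that does not depend on PAT-9 may contribute and was not tested, as neither the control nor another factor was analysed here, nor was any biological explanation; if the strain label with mNG holds, the antibody against GFP may not have captured PAT-9 at all.

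The second pattern is the excess on chromosome X. tRNA genes are concentrated there (276 of 612), but without summits near small RNA genes X still held 113 of 494 peaks, an odds ratio of 1.69 (1.35 to 2.09) against 2.03 with them. Stratified by GC content the odds ratio was 1.70 (1.43 to 2.02). Neither alone explains the whole excess, and each may explain part of it. They were not tested jointly, so whether an excess on X remains after both stays open. Peaks at other noncoding RNA genes were also kept when small RNA genes were left out. Signal that does not depend on PAT-9 was not tested, and no biological explanation was tested.

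The third pattern is the binding of muscle genes. The listed markers of other tissues were not bound as often. A peak was present at 17 of 87 muscle genes and 2 of 80 markers of pharynx, neurons, hypodermis, intestine and germline (odds ratio 9.37, 2.11 to 86.5). With double the number of peaks 31 of 87 and 10 of 80 had one (3.84, 1.66 to 9.58). Only genes with a pooled region in the promoter window were counted. A larger share of the listed markers of other tissues than of the muscle genes lacked such a region. Expression in late embryos was not measured, so this comparison cannot separate tissue from expression at this stage. Among promoter regions the odds ratio for muscle genes was 2.94 (1.65 to 4.92) and 2.32 (1.36 to 3.96) when stratified by GC content, so base composition does not account for it alone. A preference for promoters of abundantly expressed genes stays open, because ribosomal protein genes were bound about as often (14 of 73; odds ratio of muscle against ribosomal protein genes 1.02, 0.43 to 2.45). Ribosomal protein genes were the only stand-in for abundant expression, which was not measured, and the muscle side pooled all 4 muscle lists. The number of regions per promoter also stays open, since the sarcomere list was not called against random lists matched on it. Signal that does not depend on PAT-9 was not tested. If the strain label with mNG holds, the antibody against GFP may not have captured PAT-9 at all. PAT-9 at muscle promoters is therefore a hypothesis that these lists leave beside these other candidate explanations.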
